A study of Mus musculus with 40 samples.

How the data were processed

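Left ventricular RNA from 40 FVB/NJ mice was sequenced as stranded libraries, per the labels' protocols. The 8 groups crossed genotype (Con or ONOFF), surgery (sham or TAC) and sex, with 5 libraries each. Per the submitters' processing notes, reads were checked with FastQC 0.11.7 and MultiQC 0.8, aligned with STAR 2.7.3a to GRCm39, quantified with Salmon and handled in R 4.3.1 with DESeq2, which is named here only as listed by the submitters. The authors deposited a single table of normalized count signal, 22676 genes by 40 libraries, and every column was matched to a library through the labels. Raw counts were not used here, so neither sequencing depth nor counting intervals could be obtained. Library totals of the normalized values were 35176220 to 47653987. The annotation at hand was for another mouse genome build, so no coordinates are given, and genes are named by the symbols in the table. Of the table's genes, 41 had no symbol.

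Values were transformed as log2(value + 1), and genes with a value of at least 10 in at least 5 libraries were kept (16395). limma 3.58.1 in R 4.3.3 fitted 8 group means with an intensity trend and robust variance estimates. The 17 contrasts were the effect of TAC in each genotype, the effect of genotype in each surgery and their interaction, each averaging both sexes equally, then the 4 simple effects in each sex (8 contrasts) and the 4 differences of these between the sexes. Values of p were two-sided and adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p below 0.05 were called. A library counted as being on the side of a change when it lay beyond the mean of the same sex in the condition compared. Camera in limma tested 34 gene lists in 5 contrasts (170 tests, adjusted together) with a correlation estimated for each list, and a preset correlation of 0.01 as an alternative. The same lists were tested in the 4 contrasts between the sexes, with a separate adjustment. Percentages of called list members also used an adjustment over the list alone. The median, mean and camera direction of a list differed in sign in 17 of the 170 tests, and the lowest adjusted p among these was 0.911.

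The lists, contrasts, filter, test, alternatives and rule for named genes were fixed before the data were examined. The rule named, for each contrast averaging the sexes, the 10 largest and 10 smallest log2 changes among called genes with a mean of at least 100 in the higher condition and the same sign in both sexes, skipping predicted genes. It also took up to 4 members of each list with the smallest p, 3 higher and 3 lower genes in each contrast within a sex, and in every case Oga, Ogt, the sex-linked genes, Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1 and Postn. Some genes that the rule took are not reported here. The procedure was tested on simulated data, normal values drawn with each gene's mean and residual SD, in which planted changes of 3 sizes were recovered in part. At a planted log2 change of 1, 80.6% of 67 genes were recovered for TAC in Con mice, 82.1% for TAC in ONOFF mice, 73.1% and 76.1% for genotype in sham and TAC mice, 67.2% for the interaction and 41.8% to 47.8% for the 4 sex differences. At a log2 change of 0.5 these were 52.2%, 46.3%, 44.8%, 49.3%, 28.4% and 5.97% to 16.4%.

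Alternatives were a pseudocount of 10, no filter, a mean of at least 50 (12699 genes), TMM rescaling, quantile normalization, library weights, only the groups compared, an additive sex term, replicate number as a block, a number in the library names as a random block (statmod 1.5.0), the preset correlation, and leaving out each of the 40 libraries. Leaving out libraries with many zeros or without Xist was chosen after seeing the data. For each contrast, 100 splits of the libraries were drawn with a fixed seed, the real split included. Tables were handled with the package data.table (version 1.17.8). Figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Replicate numbers were not stated to pair mice across groups, and no sequencing batch was given.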

Results

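Left ventricles of FVB/NJ mice were profiled by bulk RNA sequencing in 40 libraries, 5 in each of 8 groups. The groups crossed genotype, surgery and sex. Control mice are called Con. Mice called ONOFF carried an inducible, heart-restricted dominant-negative form of OGA, the enzyme that removes the sugar O-GlcNAc from proteins. Per the labels' protocols, doxycycline food was given for 2 weeks and withdrawn for 2 weeks. The mice then had transverse aortic constriction (TAC), a band on the aorta that overloads the ventricle with pressure, or a sham operation, and tissue was taken 9 weeks later. The design addressed whether a temporary induction meant to raise O-GlcNAc, stopped before surgery, altered the ventricle with and without pressure overload. Neither O-GlcNAc nor the end of transgene expression was measured in the table. Every condition (genotype and surgery) held 10 libraries, 5 of each sex.

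The deposited values summed to between 35176220 and 47653987 per library (median 40773814), and 16395 genes were tested. Sequencing depth before normalization is unknown. In 3 control sham libraries, Con Sham F replicates 3 and 5 and Con Sham M replicate 4, 6045, 5782 and 6920 genes were listed at 0, against 2635 to 4594 in the other 37 libraries. The 5th percentile of their values above 0 was 4.21 to 8.87, against 0.798 to 2.41 elsewhere. Xist, the RNA that coats the inactive X chromosome, was 1123 to 3274 in 18 female libraries but 51.7 and 6.72 in Con TAC F replicates 2 and 3, and 2.61 to 87.7 in males. The summed values of 4 Y-linked genes (Ddx3y, Kdm5d, Uty and Eif2s3y) were 15.96 and 12.8 in those 2 libraries, 8.2 to 72.9 in the 18 other females and 2405 to 5826 in males. Both sets were kept. Mitochondrially encoded transcripts made up 8.28% (Con TAC M replicate 1) to 22.1% of the values.

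**Figure D1:**
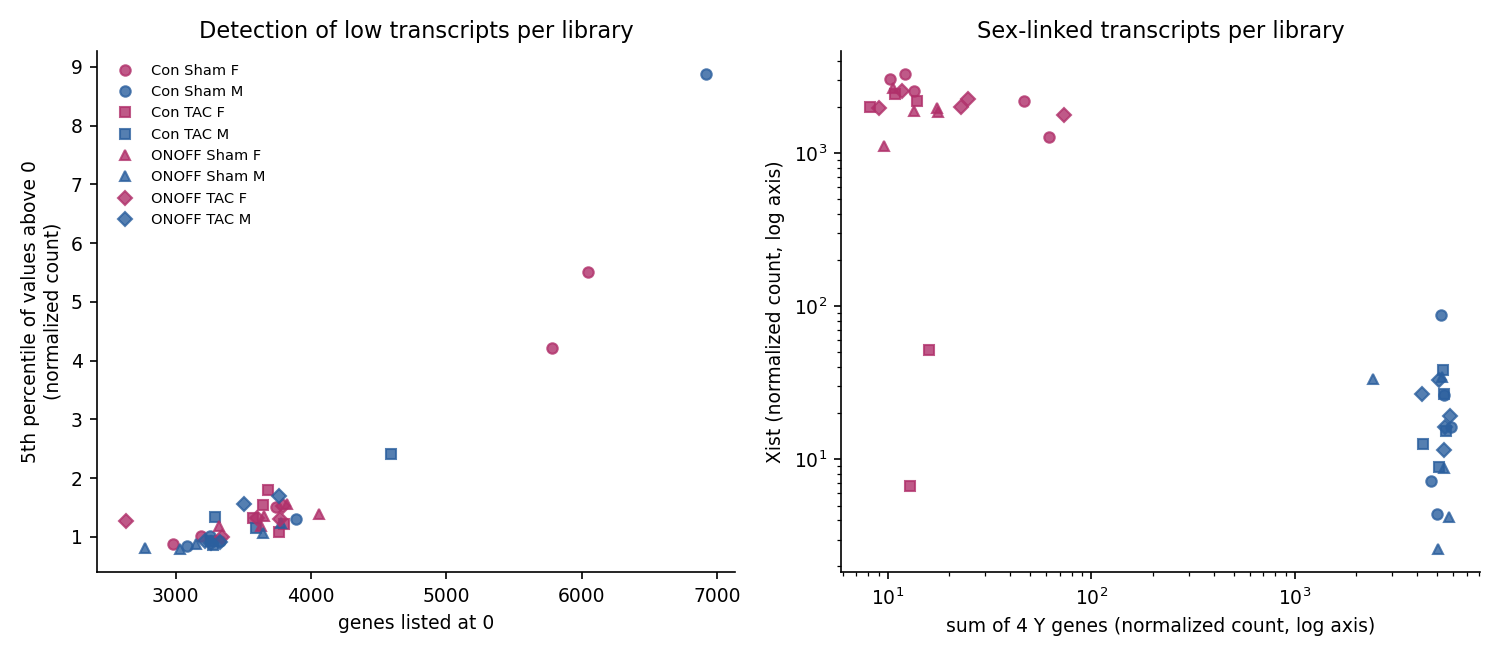
Left, the number of genes listed at 0 against the 5th percentile of the values above 0 (normalized counts), 1 point per library, where 3 control sham libraries lie apart at 5782 to 6920 genes. Right, Xist against the sum of 4 Y-linked genes on log axes (normalized counts), where 2 libraries from female Con TAC mice have Xist values of 51.7 and 6.72 with Y-gene sums of 15.96 and 12.8.

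Oga, the gene for the enzyme whose dominant-negative form was induced, was higher in ONOFF than in Con sham ventricles, 5778 ± 1750 against 3121 ± 263 normalized counts (SD, n = 10 each). The change was 1.78-fold (log2 0.83, SE 0.117, limma adjusted p = 0.000295, higher in 9 of 10 ONOFF libraries). After TAC, Oga fell in ONOFF mice to 3816 ± 767 (log2 change −0.56, SE 0.117, adjusted p = 0.000413, lower in 9 of 10). It then stood above the Con TAC value of 2988 ± 366 by 0.34, which did not pass (adjusted p = 0.0645, higher in 10 of 10). The difference between the TAC effects of both genotypes was −0.49 (SE 0.165) and did not pass either (adjusted p = 0.192). Within ONOFF sham mice, Oga ranged from 3019 to 6102 in females and from 3878 to 8294 in males. Mean Oga in ONOFF females was 4884 in sham and 4105 in TAC libraries, and in ONOFF males 6671 and 3528. Con sham means were 3311 in females and 2931 in males. The tests of the difference between the sexes did not call Oga. The table has 1 Oga value per library, so reads from the transgene and from the endogenous gene could not be separated, and transgene expression that persisted after withdrawal of doxycycline is not excluded. Ogt, the gene for the enzyme that adds O-GlcNAc, was 2367 ± 316, 2186 ± 361, 2165 ± 447 and 2012 ± 250 (SD, n = 10 each) in Con sham, Con TAC, ONOFF sham and ONOFF TAC, and no contrast of it passed. Over the 14 tested members of the hexosamine pathway and O-GlcNAc cycling list, 1 was higher and 0 lower in ONOFF sham mice (adjusted over the list alone, 1 and 0). That list did not move against other genes (camera adjusted p = 0.696 with an estimated correlation).

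**Figure D2:**
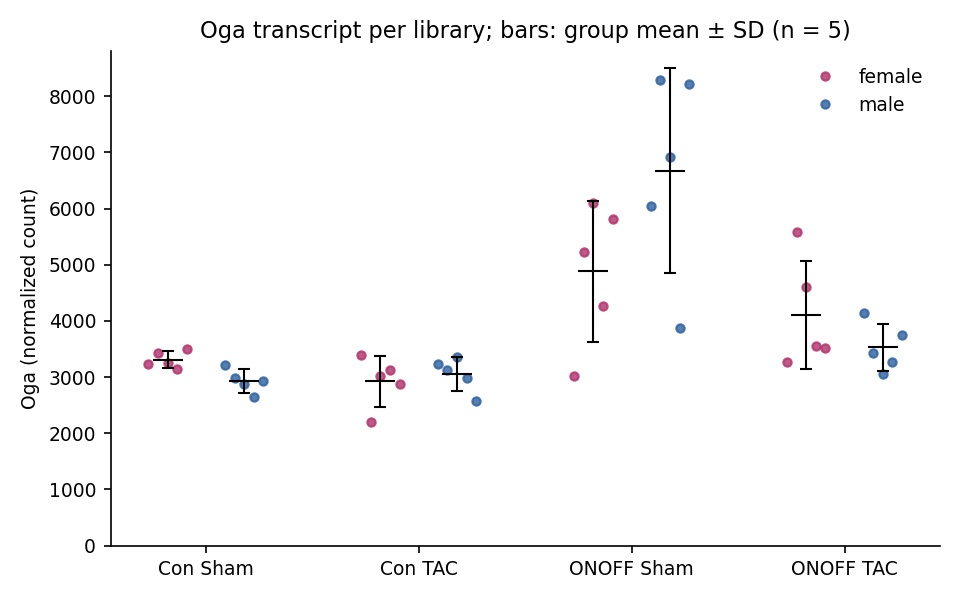
Oga normalized count in each library (points, females and males) by condition, with the mean and SD of each group of 5 as bars. ONOFF sham libraries averaged 5778, ONOFF TAC libraries 3816, and the Con groups 3121 and 2988.

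In Con mice after TAC, Nppa, which encodes atrial natriuretic peptide, rose 4.89-fold (log2 2.29, SE 0.313, adjusted p = 1.33e-05), from 9399 ± 3657 to 48575 ± 26160 normalized counts (SD, n = 10 each). Acta1, skeletal alpha-actin of the fetal heart, rose 5.198-fold (2.38, SE 0.232, adjusted p = 2.25e-08), and Nppb, B-type natriuretic peptide, rose 2.91-fold (1.54, SE 0.188, adjusted p = 1.82e-06). The stress-induced secreted factor Gdf15 rose by 2.61 on the log2 scale. The transcription factors Tbx15 (2.75), Etv4 (1.93) and Nr4a3 (1.89), the transcription cofactor Vgll2 (2.01), the growth factor Fgf6 (1.95) and the tubulin Tubb3 (1.86) were also among the largest rises. Falls included the Wnt antagonist Sfrp5 (−2.72), the water channel Aqp4 (−2.22), the mitotic protein gene Cenpf (−2.03), the protease Tmprss13 (−1.76), the acyl-CoA thioesterase Acot1 (−1.55), the GABA receptor subunit Gabrg3 (−1.43), the chloride channel Clcn1 (−1.39), Rtl3 (−1.38) and the collagen Col11a2 (−1.23). Of these genes with Nppb, all changed in 10 of 10 TAC libraries except Vgll2, Cenpf and Tmprss13 (9 of 10) and Tubb3 (8 of 10). The matrix gene Postn rose by 0.84 (SE 0.218, adjusted p = 0.0159, 10 of 10). Values for Col1a1 (0.59, adjusted p = 0.0704), the slow myosin gene Myh7 (0.18, 0.652) and the fast myosin gene Myh6 (−0.12, 0.703) did not pass. In all, 519 genes were higher and 429 lower by limma. The call of Etv4 was lost without Con Sham M replicate 4 (adjusted p = 0.053), and that of Tmprss13 without Con Sham F replicate 3 (0.051), Con TAC F replicate 2 (0.0605) or Con TAC M replicate 2 (0.0663). Col11a2 lost its call in 9 and Tubb3 in 26 of 40 single omissions, Postn, Tmprss13, Acot1 and Tubb3 lost theirs without the 3 control sham libraries with many zeros and without the 2 Xist-poor libraries, Col11a2 without the latter, and the total fell to 581 without the 2 Xist-poor libraries, to 598 without all 5 and to 495 (253 higher and 242 lower) with only the groups compared.

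Among the lists, the fetal and hypertrophy genes rose as a group in Con TAC ventricles: 9 of 16 members were higher and 0 lower (10 and 0 adjusted over the list alone), including the stress-responsive Ankrd1 (1.15) and the actin-binding Xirp2 (0.88). It was the 1 list of 34 that passed there (camera adjusted p = 0.0047 with an estimated correlation). Calcium handling and ion channel genes went down in 11 of 26 cases, with 0 higher (12 lower and 1 higher adjusted over the list alone), among them the potassium channel genes Kcnj2 (−0.82), Kcnv2 (−1.005) and Kcnh2 (−0.58). As a list they did not pass (adjusted p = 0.133 with an estimated correlation). Fatty acid oxidation genes were lower in 12 of 38 cases and higher in 0 (23 lower and 0 higher adjusted over the list alone), including Acaa2 (−0.58) and Hadha (−0.36), which encode enzymes of the beta-oxidation spiral (list adjusted p = 0.168 with an estimated correlation). Of the extracellular matrix genes, 14 of 53 were higher and 1 lower (30 and 1 adjusted over the list alone), with Col8a1 at 0.90 and Cilp at 1.74 (adjusted p = 0.441 with an estimated correlation). TCA cycle genes counted 4 of 20 lower (10 alone, adjusted p = 0.262 with an estimated correlation), and oxidative phosphorylation genes 2 of 51 lower (2 alone, adjusted p = 0.901). Mitochondrially encoded transcripts had 2 of 15 lower in the same libraries (8 alone, adjusted p = 0.454 with an estimated correlation). Without single libraries, the p of the fetal and hypertrophy list ranged from 0.00202 to 0.0123, and without the 2 Xist-poor libraries 2 lists passed.

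In ONOFF mice, TAC changed 3480 genes, 1749 higher and 1731 lower (5266 genes with library weights). Nppa rose 13.0-fold (log2 3.71, SE 0.313, adjusted p = 1.66e-10), from 11471 ± 6848 to 144243 ± 61993 normalized counts (SD, n = 10 each), and Acta1 rose 7.38-fold (2.88, SE 0.232, adjusted p = 3.96e-11). Postn, a matricellular protein gene of activated fibroblasts, rose 4.42-fold (2.14, SE 0.218, adjusted p = 3.55e-09) from 2550 ± 497 to 11887 ± 4556. Cilp, another matrix protein gene, rose 9.73-fold (3.28, SE 0.333, adjusted p = 4.35e-09), and the collagen gene Col1a1 rose 2.16-fold (1.11, SE 0.197, adjusted p = 5.01e-05). The largest rises also held the serpin Serpinb1c (4.00), the metalloprotease Adamts20 (3.58), Gdf15 (3.31), the muscle ankyrin repeat gene Ankrd2 (3.01), the matrix gene Frem1 (2.94) and the ryanodine receptor gene Ryr3 (2.87). Falls included Aqp4 (−3.16), Gabrg3 (−2.53), the chemokine Ccl11 (−2.39), the carboxylesterase Ces1d (−2.38), the kinase Sbk2 (−2.20), the glycolytic regulator Pfkfb1 (−2.19), the ephrin Efnb3 (−2.18), the phosphorylase kinase subunit Phkg1 (−2.15) and Uckl1os (−2.15). Each of these was displaced in 10 of 10 TAC libraries, except Sbk2 in 9 of 10, and none was lost without any single library. Nppb rose by 1.87 (10 of 10). Myh6 fell by 0.46 (adjusted p = 0.0139, 8 of 10), a call that was lost under quantile normalization, and Myh7 at 0.37 did not pass (adjusted p = 0.173).

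**Figure D3:**
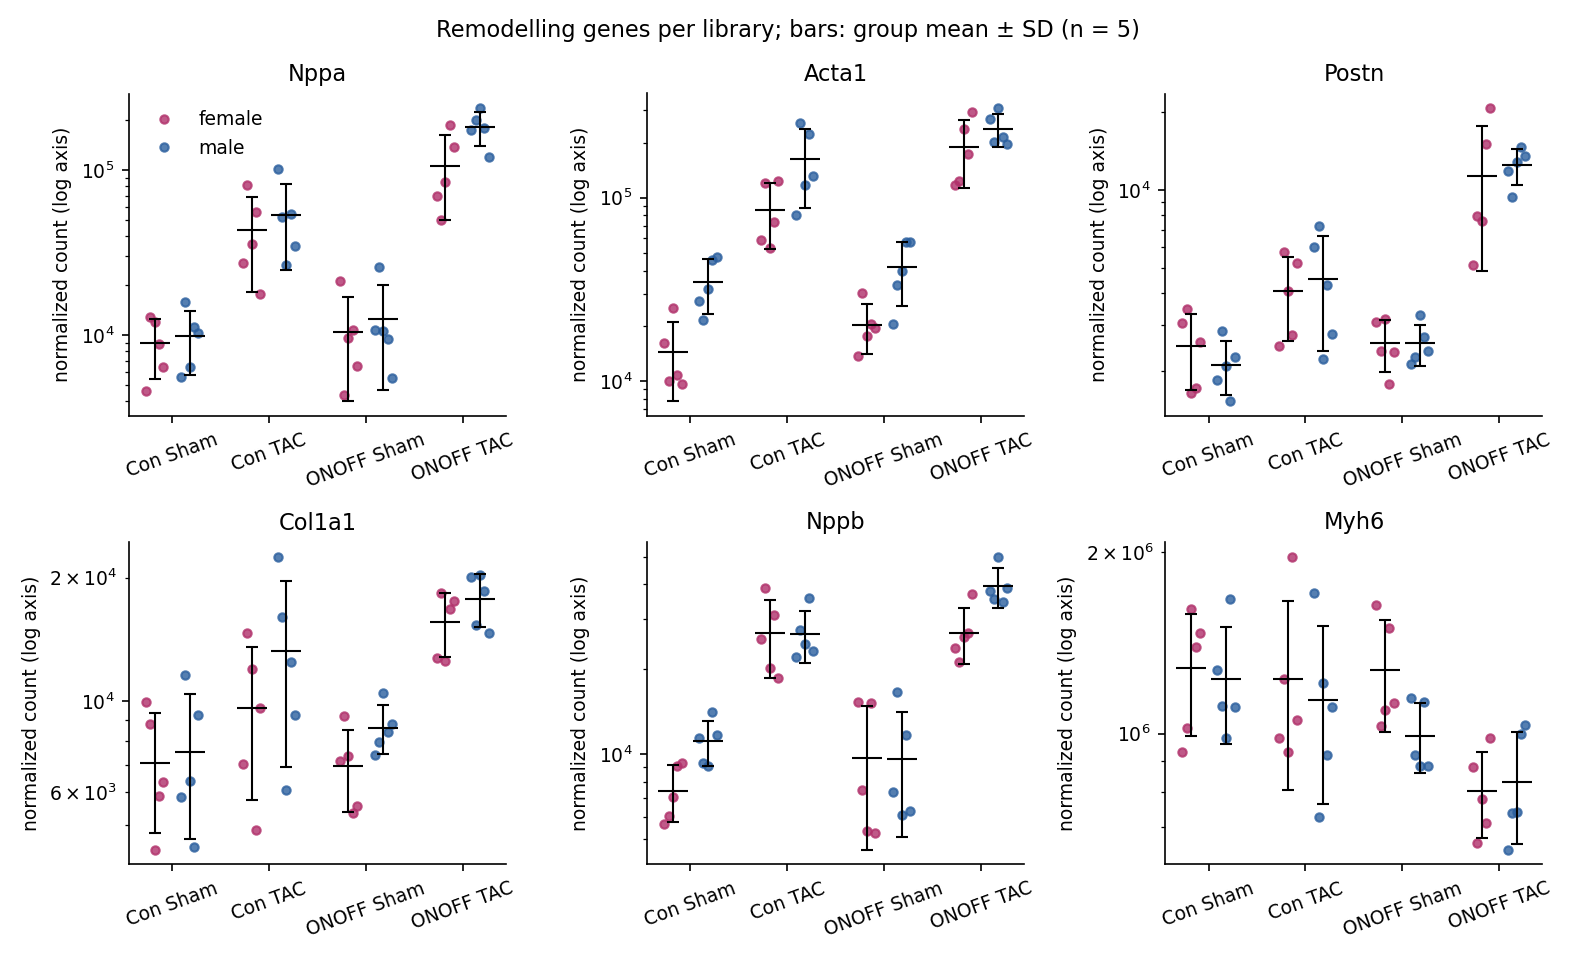
Normalized counts of 6 remodelling genes in each library on log axes, females and males apart, with the mean and SD of each group of 5 as bars. Mean Nppa was 9399 in Con sham, 48575 in Con TAC, 11471 in ONOFF sham and 144243 in ONOFF TAC libraries.

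After TAC in ONOFF mice, 2 of the 34 lists passed, and several others had many called members without passing. Extracellular matrix genes were higher in 45 of 53 cases and lower in 1 (48 and 1 adjusted over the list alone), with the proteoglycan Bgn at 1.35 and Col8a1 at 1.86, although the list itself did not pass (camera adjusted p = 0.101 with an estimated correlation). Fetal and hypertrophy genes were higher in 11 of 16 and lower in 0 (11 and 0 adjusted over the list alone, adjusted p = 0.0047 with an estimated correlation), with Xirp2 at 1.58 and Ankrd1 at 1.49. Genes that break down branched-chain amino acids and ketones fell as a group, 17 of 20 lower and 1 higher (17 and 1 adjusted over the list alone, adjusted p = 0.0278 with an estimated correlation). Among them were the phosphatase Ppm1k (−0.98), Mccc2 (−0.66) and Auh (−0.48). Fatty acid oxidation genes were lower in 26 of 38 cases (30 alone, adjusted p = 0.118 with an estimated correlation), led by Acaa2 (−1.23), Decr1 (−0.87) and Acadvl (−0.60). Oxidative phosphorylation genes were lower in 41 of 51 (50 alone, adjusted p = 0.441) and TCA cycle genes in 17 of 20 (17 alone, adjusted p = 0.118), with Ndufs1 at −0.46, Sdha at −0.50 and citrate synthase Cs at −0.46, and 0 members of these lists were higher. Calcium handling and ion channel genes were lower in 15 of 26 and higher in 0 (15 and 1 alone, adjusted p = 0.145), including Kcnv2 (−1.73) and Kcnj3 (−1.37). Adult sarcomere genes split, 2 higher and 7 lower of 18 (2 and 8 alone, adjusted p = 0.76), with Tnni3 at −0.69 and Mybpc3 at 0.30. TGF-beta and secreted stress factors had 12 of 25 higher and 3 lower (12 and 3 alone, adjusted p = 0.101), with Tgfb2 at 1.71 and Ltbp1 at −0.73. Mitochondrially encoded transcripts were lower in 7 of 15 (9 alone, adjusted p = 0.652), and cardiac fibroblast markers were higher in 8 of 18 and lower in 2 (9 and 3 alone, adjusted p = 0.701), with Meox1 at 1.35 and Scara5 at −0.87. With the preset correlation of 0.01, camera called 12, 13, 8, 12 and 9 of the 34 lists in the Con TAC, ONOFF TAC, sham genotype, TAC genotype and interaction contrasts. Of these calls, the fetal and hypertrophy list in the Con TAC, ONOFF TAC and TAC genotype contrasts and the branched-chain amino acid and ketone list in the ONOFF TAC contrast held with an estimated correlation. Without the 3 libraries with many zeros, the branched-chain amino acid and ketone list did not pass for TAC in ONOFF mice and 1 list was left, and without the 2 Xist-poor libraries 6 passed. The ion channel list also passed in ONOFF mice without Con TAC F replicate 2 (adjusted p = 0.0406 with an estimated correlation).

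**Figure D4:**
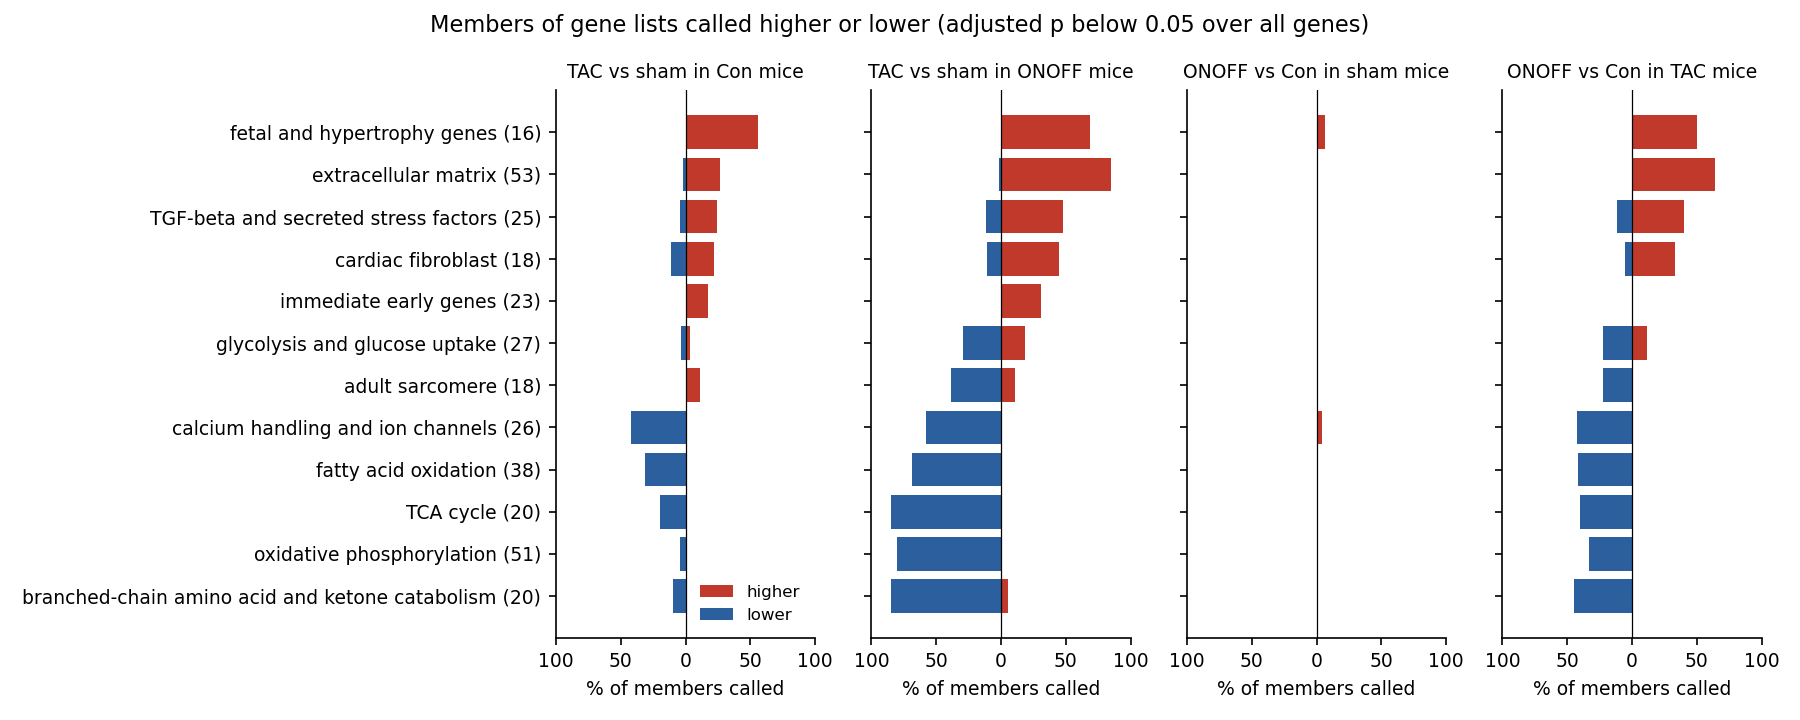
Percentage of the tested members of 12 gene lists (number of members in brackets) called higher or lower at an adjusted p below 0.05 over all genes, in 4 comparisons. In ONOFF mice 45 of 53 extracellular matrix genes were higher and 41 of 51 oxidative phosphorylation genes were lower after TAC, while 2 of the members shown differed between genotypes in sham mice.

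The comparison of sham-operated ONOFF and Con ventricles addressed the genotype difference without pressure overload, after doxycycline had been withdrawn. Uchl1, a ubiquitin hydrolase gene, was 1.84-fold higher (log2 0.88, SE 0.133, adjusted p = 0.000685, 10 of 10 libraries), Oga was higher as given above, and Ednra, an endothelin receptor gene, was lower (−0.48, SE 0.082, adjusted p = 0.0043, 10 of 10). The kinase gene Ptk2b was higher by 0.94 (adjusted p = 0.0221, 9 of 10) and the growth-factor adaptor Grb10 lower by −0.45 (adjusted p = 0.0221, 10 of 10). Dnai1 (0.71), Cryzl2 (0.67), Morn4 (0.67), Metrn (0.66), Ccl27a (0.59), Enho (0.50), Mapk12 (0.46) and the potassium channel regulator Abcc9 (−0.47) were the other genes the naming rule took, with adjusted p between 0.0223 and 0.0455. Nppa (0.19, adjusted p = 0.928), Nppb (−0.03, 0.986), Acta1 (0.39, 0.694), Postn (0.18, 0.9) and Col1a1 (0.14, 0.918) did not pass. The total was 19 higher and 4 lower, and 1415 genes had an unadjusted p below 0.05. With only the groups compared it was 4 higher and 8 lower (8 of the 23 calls kept), and with a replicate block 4 and 4 (7 kept), so the excess of higher genes was not stable. The total was 13 with no filter and 47 with library weights. Of the 34 lists none passed (lowest camera adjusted p = 0.332 with an estimated correlation, vascular endothelium), and members were called in 4 lists, 1 each: Uchl1, Oga, Abcc9 and the pacemaker channel gene Hcn2 (0.42). The fetal and hypertrophy list had 1 of 16 higher (2 alone, adjusted p = 0.454 with an estimated correlation). Only the calls of Uchl1, Oga and Ednra held without any single library. Ptk2b was lost without Con Sham F replicate 4 (0.0566), ONOFF Sham F replicate 4 (0.0754) or ONOFF Sham M replicate 4 (0.0512), Grb10 without Con Sham F replicate 4 (0.0522), Con Sham M replicate 2 (0.0565) or ONOFF Sham F replicate 4 (0.065), and the other 8 named genes and Hcn2 in 7 to 27 of 40 omissions. The total moved to 40, 49, 11, 4 and 7 without Con Sham F replicates 1, 2, 3, 4 and 5, to 13, 6, 46 and 9 without Con Sham M replicates 1, 2, 3 and 5, to 45, 6, 3 and 9 without ONOFF Sham F replicates 1, 2, 4 and 5, and to 11, 14, 13, 6 and 14 without ONOFF Sham M replicates 1 to 5. Without the 3 libraries with many zeros 2 calls were left, and Ednra was not among them.

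After TAC, 1306 genes differed between genotypes, 679 higher and 627 lower in ONOFF ventricles (2355 with library weights). Nppa was 3.04-fold higher than in Con TAC mice (log2 1.60, SE 0.313, adjusted p = 0.00102) and Postn 2.79-fold higher (1.48, SE 0.218, adjusted p = 4.45e-05). Cilp was 4.16-fold higher (2.06, SE 0.333, adjusted p = 0.000137), and Acta1 1.86-fold higher (0.90, SE 0.232, adjusted p = 0.0122). Adamts20 (2.73), Ankrd2 (2.63), the collagen genes Col12a1 (2.45) and Col22a1 (1.98), the endothelin-converting enzyme Ece2 (2.38), the cholesterol transporter Star (2.36), Ryr3 (2.20), Mlph (2.07) and the mechanosensitive channel Piezo2 (1.96) made up the rest of the 10 largest. Lower genes were led by Ces1d (−2.09), the platelet chemokine Ppbp (−1.72), Prr33 (−1.58, adjusted p = 4.48e-06), Efnb3 (−1.46, SE 0.176, adjusted p = 2.15e-06), Pfkfb1 (−1.46), Snai3 (−1.34), the myosin kinase Mylk4 (−1.33), proenkephalin Penk (−1.32), Slc9a2 (−1.25) and neurogranin Nrgn (−1.25). Each was displaced in 10 of 10 ONOFF TAC libraries, except Piezo2, Snai3 and Mylk4 (9 of 10) and Penk and Slc9a2 (8 of 10). Uchl1 was 1.29 higher (adjusted p = 1.25e-07), and the change of its genotype difference with TAC did not pass (0.41, adjusted p = 0.381). Col1a1 was higher by 0.67 (adjusted p = 0.0306, 10 of 10) and Myh6 lower by −0.50 (adjusted p = 0.0219, 10 of 10), while Nppb (0.30, adjusted p = 0.393) and Myh7 (−0.01, 0.992) did not pass. Myh6 lost its call without Con TAC F replicate 4 (0.0602) or Con TAC M replicate 1 (0.0542). Col1a1 lost it without Con TAC F replicates 1 (0.0548) and 4 (0.0784), Con TAC M replicates 3 (0.0813) and 5 (0.0626), ONOFF TAC F replicates 2 (0.054), 4 (0.0554) and 5 (0.0539) or ONOFF TAC M replicates 1 (0.0511) and 3 (0.0554), and Ece2 lost it in 13 of 40 omissions.

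In the same comparison by lists, 1 of 34 passed. Extracellular matrix genes were higher in 34 of 53 cases and lower in 0 (46 and 0 adjusted over the list alone), with Bgn at 0.94 and the thrombospondin Thbs4 at 1.64 (camera adjusted p = 0.0914 with an estimated correlation). Fetal and hypertrophy genes were higher in 8 of 16 and lower in 0 (8 and 0 alone), with Xirp2 at 0.91 and Ankrd1 at 0.49, and this list passed (adjusted p = 0.0217 with an estimated correlation). TGF-beta and secreted stress factors were higher in 10 of 25 and lower in 3 (14 and 3 alone, adjusted p = 0.101), with Tgfb2 at 0.94 and Tgfb3 at 0.59. Oxidative phosphorylation genes were lower in 17 of 51 (47 alone, adjusted p = 0.332), fatty acid oxidation genes in 16 of 38 (25 alone, and 1 higher, adjusted p = 0.168), TCA cycle genes in 8 of 20 (17 alone, adjusted p = 0.199) and branched-chain amino acid and ketone genes in 9 of 20 (12 alone, adjusted p = 0.0615), with Ndufs1 at −0.33, Acaa2 at −0.74, Idh2 at −0.42 and Mccc2 at −0.47. Calcium handling and ion channel genes were lower in 11 of 26 and higher in 0 (16 and 2 alone, adjusted p = 0.168), including Kcnv2 (−1.08), Hrc (−0.32) and phospholamban Pln (−0.32). Adult sarcomere genes were lower in 4 of 18 (4 alone, adjusted p = 0.512), and cardiac fibroblast markers were higher in 6 of 18 and lower in 1 (9 and 1 alone, adjusted p = 0.454), with Pi16 at 0.79 and Mfap5 at 0.94. Mitochondrially encoded transcripts had 1 of 15 lower (1 alone, adjusted p = 0.911). Atrial markers had 2 higher and 1 lower of 12 (3 and 2 alone, median 0.863, adjusted p = 0.784). Mesothelial markers had 1 of 9 higher (1 alone, median 0.831, adjusted p = 0.76). Of 19 lymphocyte markers 0 were called by limma (median −0.58, camera adjusted p = 0.698). Without Con TAC F replicate 2, 5 lists passed, the matrix (0.0359), TGF-beta (0.0359), branched-chain amino acid and ketone (0.0046) and ion channel (0.0253) lists having joined. Without both Xist-poor libraries 6 passed, without the 3 libraries with many zeros 0 passed, and without all 5 it was 3.

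Effects of TAC ran in the same direction in both genotypes across most genes that moved. Across all 16395 genes, which are not independent replicates, the effects in Con and ONOFF mice, from separate libraries, correlated at Pearson r = 0.562 (0.373 in females alone, 0.463 in males alone and 0.469 without the 3 libraries with many zeros and the 2 Xist-poor libraries). Of the 519 genes higher in Con mice, 399 (76.9%) were also higher in ONOFF mice, where independent lists would share 55.4, and of the 429 lower genes 347 (80.9%) were also lower, against 45.3. Only 1 gene was called in opposite directions. The test of the difference itself called 73 genes, 39 with a positive and 34 with a negative difference in the log2 TAC effect, ONOFF minus Con. A negative difference can be a deeper fall in ONOFF mice. Ryr3 differed by 2.75 (SE 0.529, adjusted p = 0.0195), the prostaglandin transporter gene Slco2a1 by 1.31 (SE 0.224, adjusted p = 0.00481), Ttll1 by −0.85 (SE 0.161, adjusted p = 0.0195) and the homeodomain gene Hopx by −0.83 (SE 0.163, adjusted p = 0.0199). These 4 of the 29 named genes held without any single library. Postn (1.30, adjusted p = 0.0474) and the collagen cross-linking enzyme gene Lox (1.26, adjusted p = 0.0306) were also called, while Nppa (1.42, adjusted p = 0.153), Acta1 (0.51, 0.601) and Col1a1 (0.53, 0.486) were not. Matrix genes counted 5 of 53 higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 0.145 with an estimated correlation), and branched-chain amino acid and ketone genes 1 of 20 lower (10 alone, adjusted p = 0.0815). No list passed with an estimated correlation and all libraries. Lists passed under some alternatives, the TGF-beta (0.0406) and branched-chain amino acid and ketone lists (0.00597) without Con TAC F replicate 2, the fetal and hypertrophy list (0.0472) without ONOFF Sham F replicate 4, 3 lists without the 2 Xist-poor libraries, 1 without all 5 and 1 with a replicate block. Postn lost its call in 27 and Lox in 9 of 40 omissions, and all 73 genes were also called for TAC in ONOFF mice, 23 of them for TAC in Con mice. The count moved to 40, 32, 111 and 35 without Con Sham F replicates 1, 2, 3 and 5, to 13 and 18 without Con Sham M replicates 2 and 5, to 37, 129, 28, 19 and 31 without Con TAC F replicates 1 to 5 and to 139, 10 and 23 without Con TAC M replicates 2, 3 and 5. It moved to 18, 12 and 32 without ONOFF Sham F replicates 2, 4 and 5, to 16, 29, 32 and 36 without ONOFF Sham M replicates 1, 3, 4 and 5, to 250, 34, 11 and 9 without ONOFF TAC F replicates 1, 3, 4 and 5 and to 37, 10 and 40 without ONOFF TAC M replicates 1, 3 and 4. Without the libraries with many zeros it was 128, without the Xist-poor libraries 149, and without all 5 it was 440. With all libraries it was 8 with a replicate block, 32 with the number in the library names as a random block, 30 with no filter, 120 with quantile normalization and 449 with library weights.

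**Figure D5:**
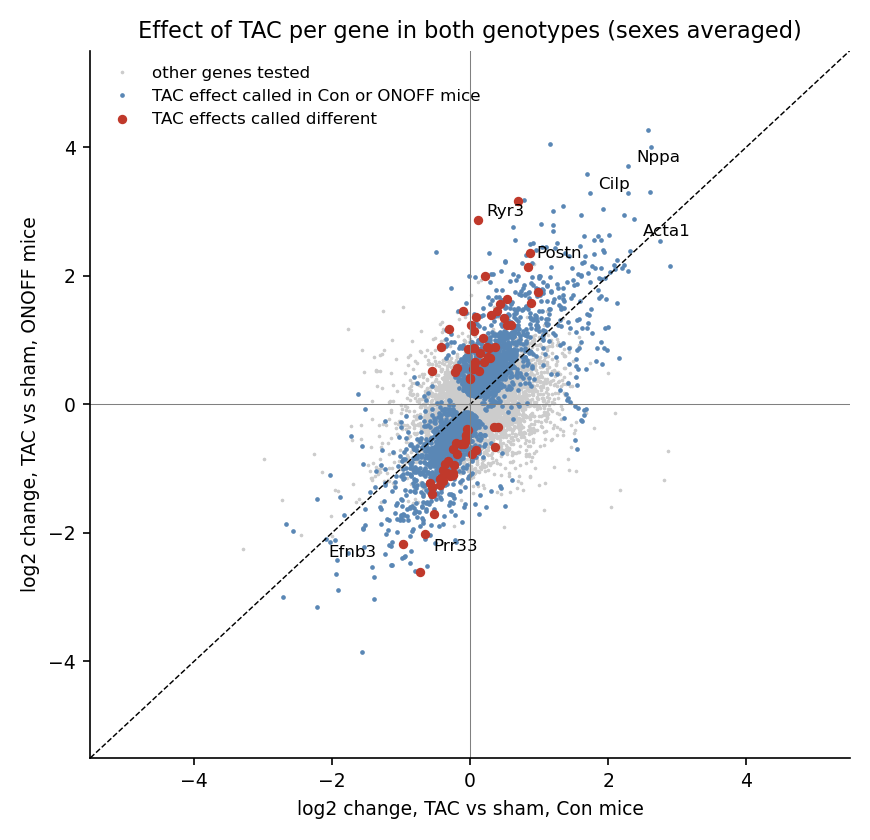
Log2 change after TAC in Con mice (horizontal) against ONOFF mice (vertical), 1 point per tested gene with the line of equal effects dashed. Red points are the 73 genes whose effects were called different, and the correlation over all genes was 0.562.

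In each sex alone, TAC called 184 genes in Con females (117 higher), 140 in Con males (81 higher), 1769 in ONOFF females (859 higher) and 1941 in ONOFF males (980 higher). Large changes in Con females were in Acta1 (2.60), Gdf15 (2.25), Cenpf (−2.21), Gabrg3 (−1.71) and Rtl3 (−1.42), and in Con males in Tbx15 (3.65), Etv4 (3.10), Gdf15 (2.97), Aqp4 (−2.66) and Phkg1 (−1.57). In ONOFF females they were in Adamts20 (3.86), Nppa (3.38), Cilp (3.36), Gabrg3 (−2.58) and Acot1 (−2.42), and in ONOFF males in Serpinb1c (4.82), the synaptotagmin Syt13 (4.05), Nppa (4.03), Aqp4 (−4.18) and Ccl11 (−2.89). Between genotypes after TAC, 28 genes were called in females and 642 in males. Thbs4 (1.67), Postn (1.37), Svep1 (1.19), Efnb3 (−1.15), Il15 (−0.87) and Fitm1 (−0.78) led in females. Adamts20 (3.39), Syt13 (2.98), Ankrd2 (2.90), Ces1d (−2.48), Prr33 (−2.27) and Tmem150c (−2.11) led in males. In sham mice, Oga (1.14, SE 0.165, adjusted p = 0.00055), the cytidine deaminase Cda (2.80, adjusted p = 0.0231) and Ptk2b (1.40, adjusted p = 0.0231) were called in males and 0 genes by limma in females, where 1149 had an unadjusted p below 0.05 and Uchl1 stood at 0.90 (adjusted p = 0.119). The tests of the difference between the sexes called 0 genes by limma for each of the 4 effects, with 540, 862, 512 and 656 genes at an unadjusted p below 0.05 for TAC in Con, TAC in ONOFF, genotype in sham and genotype in TAC mice. The smallest p belonged to Akain1, whose genotype effect in sham mice differed by −3.85 (adjusted p = 0.0563). No list differed between sexes (lowest camera adjusted p = 0.965 with an estimated correlation). The counts in separate sexes are therefore no evidence that effects differed between them.

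The counts by sex moved with the libraries left out. Without the 2 Xist-poor libraries, which belong to this group, the Con female count fell to 27 (25 of the 184 calls kept), without the 3 libraries with many zeros to 67 and without all 5 to 20. The same omissions gave 120, 85 and 245 genes for genotype in TAC females, and without all 5 it was 964 in TAC males. In sham males 1 gene was called without the 3 libraries or all 5. With only the groups compared, 2 genes were called in sham males, both lower, and the calls of Oga, Cda and Ptk2b there were lost. That setting called 0 genes by limma for genotype in TAC females, so the 6 named there were lost too, and it called 33 and 49 genes for TAC in Con females and males. Library weights gave 119 and 717 genes for TAC in Con females and males, 2794 and 4071 in ONOFF females and males, 1 and 18 for genotype in sham females and males and 333 and 1584 in TAC females and males. A replicate block gave 122 for Con females and 5 for genotype in TAC females, which also moved to 62 with a pseudocount of 10, 49 with a mean of at least 50, 76 with quantile normalization and 6 with the number in the library names as a random block. The mean of at least 50, quantile normalization and that random block each gave 2 genes for sham females. The Con female count moved to 56 without Con TAC F replicate 2, 108 without Con TAC F replicate 5, and 112 and 88 without Con Sham F replicates 4 and 5. That of Con males moved to 77 and 84 without Con Sham M replicates 1 and 4, and to 79, 51, 264 and 58 without Con TAC M replicates 1 to 4. For ONOFF females it was 1150 without ONOFF TAC F replicate 4. The genotype count after TAC in females moved to 119, 8, 6 and 12 without Con TAC F replicates 2 to 5, to 228, 15, 7, 0 and 0 without ONOFF TAC F replicates 1 to 5, to 43 without ONOFF TAC M replicate 3 or Con Sham F replicate 3, to 61 and 59 without Con TAC M replicates 2 and 3, and to 62 without Con Sham M replicate 4. In males it moved to 247 and 319 without Con TAC M replicates 3 and 5, and to 374, 404 and 418 without ONOFF TAC M replicates 3 to 5. In sham females 1 to 5 genes were called without Con Sham M replicates 1 (1), 3 (2), 4 (3) or 5 (1), Con Sham F replicates 2 (2) or 4 (5), or ONOFF TAC F replicates 1 (1) or 5 (2). In sham males 1 gene was called without Con Sham M replicate 1 or 4 or ONOFF Sham M replicate 2, 3 or 4. The sex difference of the sham genotype effect called 1, 1, 1 and 2 genes without Con Sham M replicate 1, Con Sham M replicate 3, Con TAC M replicate 2 and Con Sham F replicate 4. Of the named genes, Gdf15 in Con females lost its call without Con TAC F replicate 2 (adjusted p = 0.0727), and Cenpf, Gabrg3, Etv4, Phkg1, Cda, Ptk2b, Adamts20, Syt13, Ankrd2 and the 6 named in females after TAC lost theirs in 3 to 23 of 40 omissions.

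Overlaps between sexes use separate mice. All groups shared 1 variance estimate per gene, and genes are not independent, so the counts for independent lists are only a reference. Of the 339 genes higher in ONOFF than in Con males after TAC, 217 (64.0%) were called higher by TAC in ONOFF females, where independent lists would share 17.8. Of the 303 lower genes, 182 (60.1%) were called lower by TAC in ONOFF females, against 16.8. All 18 genes higher in ONOFF than in Con females after TAC were called higher by TAC in ONOFF males, and 8 of the 10 lower genes were called lower there. TAC in ONOFF males and females shared 505 higher genes (51.3 if independent) and 477 lower genes (53.3). In Con mice the sexes shared 37 of the 81 genes higher in males (0.578 if independent) and 16 of the 59 lower (0.241).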

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

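The tests of Oga without the 3 control sham libraries and against the adult sarcomere list, the 3 tests on the Xist-poor libraries and the test of fewer distinct molecules were chosen after the result was seen.

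Oga was higher in ONOFF than in Con sham mice and fell after TAC in ONOFF mice. The higher value in sham mice did not come from the 3 control sham libraries with many zeros, since it was 0.819 without them. Whether Oga tracked a cardiomyocyte gene was examined with 1 such gene, Myh6. Its deviations from the group means ran opposite to those of Oga across the 20 ONOFF libraries (Pearson r = −0.656, permutation p = 0.00186, Spearman rho = −0.617, permutation p = 0.00585, and r = −0.582 without the 2 farthest libraries). The correlation was −0.827 in sham and −0.461 in TAC libraries. Oga thus did not rise with Myh6 within groups. No other gene was compared in this way, so differences between libraries that moved many genes could have hidden such a relation. The correlation also cannot decide on the fall of Oga after TAC, since group means were removed first. Mean Myh6 also fell, from 1133717 in ONOFF sham to 817154 in ONOFF TAC libraries. A lower share of cardiomyocyte RNA after TAC could contribute and cannot be told apart. The adult sarcomere list had a median of −0.201 (bootstrap interval over its members −0.399 to −0.025). Oga changed by −0.556 (limma interval over mice −0.792 to −0.32). The first interval treats genes as separate draws and does not measure the spread between mice, so the 2 are not alike. Whether the values include transgene reads, and whether the endogenous gene changed, was not tested.

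Xist was almost absent from 2 libraries labelled as female Con TAC mice. Mislabelled males are argued against, since their Y-gene sums were at most 0.664% of the lowest male library, and poor detection is argued against by 3643 genes at 0 at most, inside the range of other libraries. A single X chromosome, or a second X without inactivation, could leave Xist low. Genes escaping inactivation averaged −0.752 (log2) against the 18 other females, which ranged from 11.16 to 11.93. Both libraries lay below that range, with 1 library (11.09) inside the male range of 10.54 to 11.2 and the other below it. The low values argue against a second X without inactivation, which would not lower these genes. The margin was narrow in the library at 11.09. A single X chromosome is not established, since the other library lay below the male range as well. No biological explanation from the design was tested.

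Genes at 0 were more numerous in 3 Con sham libraries. Lower sequencing depth is consistent with the raised 5th percentile of their values above 0, at least 4.21 against at most 2.41 elsewhere. Fewer distinct molecules may also have contributed and cannot be told apart, the residual SD of well-measured genes being at least 0.372 in the 3 libraries and up to 0.45 in others. No biological explanation was tested, and all 3 libraries are Con sham, so whatever sets them apart lies on 1 side of the sham comparison.

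A single library lay far from the other 4 of its group in 9 of 116 groups tested, where chance gives about 1 in 20. Nppa was 25876 in ONOFF Sham M replicate 2. Nppb was 49954.8 in ONOFF TAC M replicate 3. Myh6 was 1966970.0 in Con TAC F replicate 4. Con TAC M replicate 1 had Kdm5d at 233.787 and Eif2s3y at 1491.33. ONOFF Sham M replicate 2 had Ddx3y at 1194.15 and Eif2s3y at 745.657. Kdm5d (184.58) and Uty (280.178) were also lowest of its group there, so all 4 Y genes were low. Its Y-gene sum of 2404.56 was the lowest of the 20 males, whose median was 5299. The same library held the highest Oga value, 8294. It was kept, and the cause was not tested. Genes at 0 numbered 6920.0 in Con Sham M replicate 4 and 4594 in Con TAC M replicate 3.

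The effect of TAC differed between genotypes, by its own test, in 73 genes. Positive differences in the log2 TAC effect, ONOFF minus Con, were those of Ryr3 (2.754), Mlph (1.788), Thbs4 (1.496), Cysltr1 (1.477), Slco2a1 (1.311), Postn (1.302), Lox (1.263), Tmem158 (1.215), Slc22a4 (1.125) and Fhl1 (1.1). List members among them were Xirp2 (0.692), Bgn (0.852), Fbln2 (0.635), Serpine2 (0.66), Hk1 (0.402), Npr3 (0.847) and Pam (0.535). Negative differences were those of Prr33 (−1.367), Efnb3 (−1.204), Lingo3 (−1.175), Hps4 (−1.017), Ttll1 (−0.846), Cabcoco1 (−0.836), Hopx (−0.829), Lrrc4b (−0.824), Slc36a2 (−0.823), Dhrs7c (−0.797), Acaa2 (−0.642) and Acat1 (−0.344). Such a difference can be a deeper fall, as for Acaa2, which fell in both genotypes and further in ONOFF mice. Of these 29, 4 (Ryr3, Slco2a1, Ttll1 and Hopx) kept their call in all 40 single omissions, and the other 25 lost it in 1 to 32.

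Other splits of the same libraries were counted 100 at a time, the real one included. Only the real split reached its count for TAC in ONOFF mice (3480 genes, 1 split as large, highest other 1) and genotype in TAC mice (1306, 1, 740). So it was for TAC in Con males (140, 1, 84), ONOFF females (1769, 1, 998) and ONOFF males (1941, 1, 289), and for genotype in TAC males (642, 1, 213) and sham males (3, 1, 1). The 3 calls in sham males were lost with only the groups compared, and for the rest the splits argue against chance. Few other splits were as large for TAC in Con mice (948, 3, 2010), genotype in sham mice (23, 2, 123) and the interaction (73, 3, 500). Each of these 3 met the limit fixed beforehand against chance, a share of splits below 0.05. The highest other split still called more genes than the real one, so the splits alone do not exclude chance there. Nor do the splits exclude chance for TAC in Con females (184, 8, 2907) or genotype in TAC females (28, 7, 668). Males and females shared 37 higher and 16 lower genes for TAC in Con mice (0.578 and 0.241 if independent) and 11 and 8 for genotype after TAC (0.372 and 0.185). These overlaps use separate mice, but all groups shared 1 variance estimate per gene and genes are not independent. By sign, 76 of the 81 higher and 57 of the 59 lower genes of Con males moved the same way in Con females. For genotype after TAC, 327 of 339 higher and 286 of 303 lower genes of males did so in females. The direction was thus mostly shared by separate mice. Genes that move together can share a sign, so neither the overlaps nor the signs decide on chance there. For genotype in sham females (highest other 785) and the 4 sex differences (highest others 114, 2, 7 and 25) the real count was 0, so all 100 splits were as large by construction and the splits decide nothing. The highest splits for TAC in Con mice and for genotype in sham mice put the 3 control sham libraries with many zeros together, which points to a structure of the samples. Without those 3 libraries the sham genotype count was 2 and that of TAC in Con females 67.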

How the results depend on the processing

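Leaving out the libraries with many zeros, without Xist, or all 5, was chosen after seeing the data, and all other alternatives were planned. No named gene or list reversed. With only the groups compared, the calls for genotype in sham mice turned from 19 higher and 4 lower to 4 and 8, and in sham males from 3 and 0 to 0 and 2, with none of the 3 kept. The additive sex term, run for the 5 contrasts averaging the sexes, moved none of their counts by over 1.5 times, and the count for TAC in ONOFF mice was moved only by library weights. Fewer libraries or groups enter the fits that leave libraries out or use only the groups compared. For the other alternatives the cause was not tested. Raw counts were not used here, so limits from depth could not be computed.

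TMM rescaling gave 2 lists for genotype in TAC mice. A pseudocount of 10 gave 62 genes for genotype in TAC females. No filter gave 13 genes for genotype in sham mice and 30.0 for the interaction. A mean of at least 50 gave 2 for sham females and 49 for TAC females. Quantile normalization gave 120.0 for the interaction, 2 for sham females and 76 for TAC females. Library weights gave 5266 genes for TAC in ONOFF mice, 47 for genotype in sham mice, 2355 for genotype in TAC mice, 449 for the interaction, 119 and 717 for TAC in Con females and males, 2794 and 4071 for TAC in ONOFF females and males, 1 and 18 for genotype in sham females and males, and 333 and 1584 in TAC females and males. Only the groups compared gave 495 for TAC in Con mice, 12 for genotype in sham mice, 33 and 49 for TAC in Con females and males, and 0 for genotype in TAC females. The number in the library names as a random block gave 32 for the interaction, 2 for sham females, 6 for TAC females and 1 for the sex difference in the sham genotype effect. The preset correlation gave 12, 13, 8, 12 and 9 lists. The correlation of TAC effects was 0.812 over genes called in either genotype and 0.373 in females.

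Without the 3 libraries with many zeros, counts were 2 for genotype in sham mice, 128 for the interaction, 67 for TAC in Con females, 1 for sham males and 85 for TAC females, with 1 list for TAC in ONOFF mice and 0 for genotype in TAC mice. Without the 2 Xist-poor libraries, they were 581 for TAC in Con mice, 149 for the interaction, 27 for TAC in Con females and 120.0 for TAC females, with 2, 6, 6 and 3 lists for TAC in Con, TAC in ONOFF, genotype in TAC mice and the interaction. Without all 5, they were 598 for TAC in Con mice, 4 for genotype in sham mice, 440.0 for the interaction, 20.0 for TAC in Con females, 1 for sham males, 245 and 964 for TAC females and males, with 3 lists for genotype in TAC mice and 1 for the interaction.

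A replicate block on the replicate number gave 8 genes for genotype in sham mice, 8 for the interaction, 122 for TAC in Con females and 5 for TAC females, with 2 lists for genotype in TAC mice and 1 for the interaction. Residuals of libraries sharing a number correlated at 0.00431 on average over 60.0 pairs, against −0.000556 over 240.0 others. Those sharing the first number of the library name correlated at 0.0433 over 49 pairs, against −0.00268 over 651 others. Group means were removed from these residuals, so an effect of a number that coincides with a group would not show. Some name numbers shared by several libraries occurred in a single condition only.

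Leaving out 1 library at a time gave 706 to 1113 genes for TAC in Con mice, 3116 to 3675 for TAC in ONOFF mice, 3 to 49 for genotype in sham mice, 886 to 1592 for genotype in TAC mice and 9 to 250.0 for the interaction. Within sexes it gave 56 to 274 (Con females) and 51 to 264 (Con males) for TAC, 1150.0 to 2072 (ONOFF females) and 1500.0 to 2098 (ONOFF males), 0 to 5 and 1 to 4 for genotype in sham females and males, and 0 to 228 and 247 to 862 in TAC females and males. Sex differences gave 0 to 2 for the sham genotype effect and 0 for the other 3. Lists past the threshold numbered 1, 2 to 3, 0, 1 to 5 and 0 to 2. For single named genes and single list tests together, 39040.0 of these outcomes stayed on their side of the threshold, 1181 became weaker and 179 stronger. These include results that were never called. Of the named genes that were called, 51 of 74 for TAC in Con and 104 of 115 for TAC in ONOFF mice kept their call in every omission. For genotype in sham mice it was 3 of 14, for genotype in TAC mice 69 of 83 and for the interaction 4 of 29.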

Other observations

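The tests of correlation between effects in separate sexes were planned, and their repeats without the doubted libraries used omissions chosen after seeing the data.

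None of the lists not described above passed with an estimated correlation. After TAC in ONOFF mice, glycolysis and glucose uptake genes went both ways, 5 higher and 8 lower of 27 (5 and 9 adjusted over the list alone, adjusted p = 0.911 with an estimated correlation). The phosphofructokinase Pfkp rose by 1.07 and the lactate exporter Slc16a3 by 1.14, while muscle Pfkm (−0.42), the muscle enolase Eno3 (−0.68) and the insulin-responsive transporter Slc2a4 (−0.38) fell. Immediate early genes were higher in 7 of 23 (7 alone, adjusted p = 0.76), led by Egr2 (2.35) and Myc (1.14), and in 4 of 23 in Con mice (6 alone, adjusted p = 0.76). Antioxidant genes were higher in 7 and lower in 3 of 19 (8 and 3 alone, adjusted p = 0.809), with Gpx3 at 0.64 and Sod2 at −0.34. Endoplasmic reticulum stress genes had 3 higher and 1 lower of 19 (3 and 2 alone, adjusted p = 0.911), glucocorticoid targets 3 higher and 2 lower of 13 (4 and 2 alone, adjusted p = 0.94), interferon genes 3 higher of 29 (2 alone, adjusted p = 0.895) and inflammatory cytokines and receptors 4 higher and 1 lower of 30 (2 and 1 alone, adjusted p = 0.901). Circadian genes were lower in 3 of 18 (3 alone, adjusted p = 0.809), with Hlf at −1.25, and cell cycle genes in 1 of 30 (Cenpf, 1 alone, adjusted p = 0.911).

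No list of markers of other cells passed after TAC in ONOFF mice. Schwann cell and neuron markers were lower in 5 of 12 (8 alone, median −0.762, adjusted p = 0.535), including the noradrenaline enzyme Dbh (−1.39), and in 4 of 12 in Con mice (7 alone, adjusted p = 0.232). Mesothelial markers were higher in 2 of 9 (2 alone, adjusted p = 0.809), the keratins Krt18 (2.80) and Krt8 (1.33). Macrophage markers were higher in 4 of 24 (2 alone, adjusted p = 0.784), with Adgre1 at 0.65. Smooth muscle and pericyte markers had 2 higher and 3 lower of 14 (2 and 3 alone, adjusted p = 0.784), atrial markers 2 and 3 of 12 (2 and 3 alone, median −0.661, adjusted p = 0.927), and skeletal muscle markers 2 and 1 of 9 (2 and 1 alone, adjusted p = 0.911). Endothelial markers had 1 higher of 22 (Npr3, 1 alone, adjusted p = 0.911), lymphocyte markers 1 lower of 19 (Cd3g, 1 alone, adjusted p = 0.911) and neutrophil markers 1 lower of 6 (Mmp9, 1 alone, adjusted p = 0.901). Of the thymocyte (6 members, adjusted p = 0.977), adipocyte (12, median −0.515, adjusted p = 0.784) and erythrocyte markers (9, adjusted p = 0.957), 0 were called by limma. The sex label list had Tsix lower, 1 of 6 (1 alone, adjusted p = 0.938).

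Sham ONOFF hearts may carry a small part of the response that TAC evoked in control hearts. Across genes, which are not independent replicates, the sham genotype effect in females correlated with the TAC effect in Con males at 0.111, above all other splits (highest 0.0895), and that in males with Con females at 0.192, as high in 2 of 100 splits (highest other 0.198). Without the 3 control sham libraries with many zeros, these were 0.194 (as high in 2 of 56 splits) and 0.154, the latter as high in 15 splits. Without all 5 doubted libraries, the correlation in males was 0.147, as high in 21 of 100 splits. The relation in males was thus not separated from other splits once doubted libraries were left out, and those libraries could account for it.

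TAC might have driven the same genes further in ONOFF mice. The slope of ONOFF on Con effects was 0.696 over all genes and 1.03 over the 948 genes called in Con mice. Of these 948, 61.2% moved further in the same direction in ONOFF mice. Their median absolute log2 change was 0.512 in Con and 0.578 in ONOFF mice. That set was chosen by its Con effects, so the sizes are descriptive. The genotype effect after TAC correlated with the TAC effect of the other sex in Con mice at 0.214 in females (as high in 4 of 100 splits, highest other 0.264) and 0.279 in males (3 of 100, highest other 0.3). Without the 3 libraries they were 0.152 (14 splits) and 0.224 (3 splits), and without all 5 libraries 0.126 (12 of 56) and 0.144 (3), so the relation in females was not separated from other splits.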
